A study of Mus musculus with 6 samples.

How the data were processed

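Total RNA of 6 mouse EpiSC cultures, extracted with a phenol-based reagent per the labels' protocols, was measured on 6 Agilent 1-colour arrays of design 028005. Per the labels, 2 cultures each belonged to the epiblastic maintenance condition (EpiSC), to 1 day in the neural plate condition (NPC1) and to 2 days in it (NPC2), and the letters A and B mark duplicate cultures. Per the labels' protocols 100 ng of RNA was amplified and labelled with Cy3 and fragmented for 30 minutes before hybridisation. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.10.1.1 under protocol GE1_1010_Sep10, which gave each spot's processed intensity, background-subtracted and detrended within the array, its median intensity and local background intensity, and flags for signal well above background, saturation and outliers. These intensities are linear and not normalized between arrays. The authors' deposited value table holds the same processed intensity multiplied by 1 constant per array, between 2.10 and 2.41, and rounded to 1 decimal. Its scale is linear and it is not centred, and what the constant was set from is not given in the sources used here. Its medians were 52.5 and 51.3 (EpiSC A and B), 61.8 and 59.6 (NPC1 A and B) and 65.3 and 64.3 (NPC2 A and B).

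Each array holds 59305 non-control spots and 3671 control spots. Between 58.2% and 61.1% of the non-control spots were well above background, 0 were saturated, and 128 to 171 per array were marked as outliers. The median local background was 23 to 25, and the spike-in controls gave a slope of 1.00 to 1.02 against their concentration on log scales. Control spots and outlier-marked spots were left out, and with them 35 probes that had no other spot on an array. Spots of a probe were averaged, which gave 55681 probes. Gene names were taken from the reference table of assembly GRCm38.p6, used for names alone, through the RefSeq accession that the files give for a probe; of 28390 probes with such an accession 26762 matched 1 symbol, 0 matched several, and 28919 probes stayed without a name. The named probes stood for 20284 genes. Per-sample columns without a matching sample numbered 0.

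The values tested were log2 of the processed intensity minus the array's 75th percentile. A gene was represented by the probe with the highest mean over the 6 arrays among its probes well above background on both arrays of at least 1 group. Of the probes, 33546 met that condition, and 14772 genes were tested. The choice of probe matters for a few genes: probes of 1 gene changed in opposite directions, each past the test, in 14, 82 and 16 of 3900 genes with several such probes in the comparisons NPC1 against EpiSC, NPC2 against EpiSC and NPC2 against NPC1. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 fit of all 6 arrays on the 3 groups, with 3 residual and 1.9 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison at a threshold of 0.05. The error given beside a log2 change is its standard error after moderation by eBayes.

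Gene lists were tested with limma's camera, which asks whether a list's genes moved relative to all other genes, with a preset correlation between genes of 0.01 and adjustment over the 72 tests of 24 lists in 3 comparisons. The lists, with 372 members and 356 distinct genes on the array, covered naive and epiblast pluripotency, neural plate, anterior neural plate, posterior neural and axial genes, neuronal differentiation, primitive streak and mesoderm, endoderm, surface ectoderm and neural crest, fibroblast and feeder, extraembryonic and trophoblast, germ cell, Nodal signalling, FGF and ERK targets, BMP, Wnt, Notch and retinoic acid genes, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and amino acid stress, p53 targets, cell cycle and housekeeping. Some genes stand in more than 1 list: Tdgf1 (epiblast, Nodal), Cer1 (streak, Nodal), Smad7 (Nodal, BMP), T (streak, Wnt), Dll1 and Dll3 (neuronal, Notch), Msx1, Msx2, Gata3 and Dlx5 (surface ectoderm, BMP), and Hand1 (streak, extraembryonic). Camera was repeated with a correlation estimated from the residuals; limma then refers the statistic to the 3 residual degrees of freedom instead of a number near that of the genes, so part of the rise in p follows from the method. The fry test asks only whether a list's own genes move, on balance, one way.

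The genes named in the text were set by a rule: in each comparison, the 6 largest rises and 6 largest falls among called genes well above background on every array of both groups whose arrays did not overlap, and the 3 largest bounds in each direction; in each list, the 4 called members with the largest change after 2 days or in the comparison described; and 20 genes named always, among them Pou5f1, Sox1, T, Nodal, Cdh1, Actb and Gapdh. The rule took 199 genes, and the values of a few of them are not reported here. Other genes named in the text were chosen after their values were seen. In 345 of the 345 called values of named genes the arrays of the 2 groups did not overlap (33.3% by chance for a gene taken at random); the rule and the test select such genes, so this count describes them and is no separate evidence. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except for 6 alternatives, among them the split of the EpiSC arrays, and 5 gene lists in the closing section.

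The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median, the authors' value table, no filter on dim probes (20274 genes), probes above background on all 6 arrays (13552 genes), the mean of all probes of a gene, every probe by itself (33532 probes), the culture letter as a block, only the 2 groups compared, eBayes with trend and robust settings, at least 2-fold change, an adjusted p under 0.01, and each array left out in turn. The lone array left in a group was then assumed to vary like the other groups. Normexp used the median spot intensity, in place of the mean and was fitted on all spots including controls. All 6 arrays lay on 1 slide and were scanned in 1 scan, so no slide or scan block applied.

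The gene test was tested on simulated data made from the gene means and spreads of all 6 arrays (14772 genes, 200 changed, 20 draws). It was scored in NPC2 against EpiSC. It recovered 57.2%, 91.1%, 97.4% and 99.5% of genes changed by 0.5, 1, 2 and 4 log2 units, and 6.03% of its calls were false. In the data 68.9% of genes passed in that comparison, so these rates need not hold there. Camera passed a list of 15 genes shifted by 1 log2 unit in 20 of 20 draws and an unshifted list in 0. Gene means and spreads hold no correlation between genes. In the data the correlation estimated within a list ran from -0.0797 (extraembryonic and trophoblast) to 0.505 (glycolysis and hypoxia). The draws therefore cannot show how often camera falsely calls a list of correlated genes.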

Results

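Gene expression was measured in mouse epiblast stem cells (EpiSCs), a pluripotent cell type derived from the epiblast of the implanted embryo. The cells were either kept in their epiblastic maintenance condition (the EpiSC group) or placed in a neural plate developmental condition for 1 day (NPC1) or 2 days (NPC2). Each group held 2 cultures, A and B, grown from the same seed culture, so the p-values measure only the spread between these samples, which may be technical. Total RNA of each culture was labelled with Cy3 and hybridised to its own 1-colour array, and all 6 arrays lay on 1 slide. Between 58.2% and 61.1% of the 59305 non-control spots of an array were well above background, and 0 spots were saturated. The 14772 genes tested were well above background on both arrays of at least 1 group. Counts of list members cover only tested genes. The number of arrays, 2 per group, limits the precision, and the median standard error (SE) of a log2 change was 0.0682. Across genes, which are not independent replicates, duplicates correlated at r = 0.9971 to 0.9976 and arrays of different groups at r = 0.9418 to 0.98. The labels name the duplicates as separate cultures, and each was counted as its own sample. Between duplicates, 31.8% (EpiSC), 43.6% (NPC1) and 42% (NPC2) of 264 probes printed as 10 spots differed by more than the noise between spots, where 5% would by chance; separate labelling and hybridisation alone would bring such a difference. A bound, written as at least N-fold, is used where a gene was not well above background on either array of a group. It sets the bright group's mean against the dim group's mean, taken on each array as the higher of the lowest well-above-background signal and the gene's own signal. A list median given with bounds uses these values and leaves out genes well above background on no array of either group. The first principal component held 79.3% of the variance and placed NPC1 between EpiSC and NPC2, and the second, with 15.2%, set NPC1 apart from both other groups.

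The comparison of NPC1 with EpiSC asked which genes differed after 1 day in the neural plate condition. Most genes of Nodal signalling and of the primitive streak fell, while several transcription factor genes of the early neural plate rose. Tdgf1, which encodes a co-receptor of Nodal, fell 26.4-fold (log2 change -4.72 ± 0.11, adjusted p = 6.65e-05, n = 2 arrays per group here and in all values that follow). Lefty1, a secreted inhibitor and target of Nodal, fell 23.7-fold (log2 change -4.57 ± 0.059). Nodal itself fell (log2 change -3.33 ± 0.10, adjusted p = 0.000109). All 11 measured members of the Nodal list fell, with a median log2 change of -3.42, and the list passed the camera test (adjusted p = 3.57e-07; adjusted p = 0.204 with an estimated correlation). Of the 3 Tdgf1 probes, 1 gave a smaller change of -1.41.

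Of the 16 measured primitive streak and mesoderm genes, 11 fell and 0 rose. T (brachyury), a transcription factor gene of the streak, fell 17.3-fold (log2 change -4.11 ± 0.060). Gsc, a gene of the anterior streak, fell 29.2-fold and was well above background on 1 of the 2 NPC1 arrays, and Fgf8, a growth factor gene, fell 15.4-fold. Cer1, which encodes a secreted Nodal inhibitor and stands in both lists, fell 21.0-fold (adjusted p = 5.98e-05). The list's median was -2.05, or -1.63 with dim genes at their bounds, and it was called lower (adjusted p = 0.00171; adjusted p = 0.204 with an estimated correlation). Among 11 endoderm genes, 7 fell and 1 rose (Dab2, 0.19). Foxa2, a transcription factor gene of endoderm and axial midline cells, fell 17.0-fold (log2 change -4.09 ± 0.13), Sox17 fell 4.02-fold, Gata6 fell 4.38-fold, and Afp, which encodes alpha-fetoprotein, fell at least 3.66-fold. The endoderm list was called lower (median -0.956, adjusted p = 0.0283; adjusted p = 0.222 with an estimated correlation). The median was -0.552 without a filter on dim probes. Its call ended when only genes above background on all 6 arrays were tested (median -0.613, adjusted p = 0.104, range 0.00696 to 0.104 over its alternatives).

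Neural plate genes moved the other way on day 1: 11 of 21 rose and 2 fell. Sox1, a transcription factor gene expressed from the start of neural plate formation, rose 6.75-fold (log2 change 2.75 ± 0.057, adjusted p = 6.52e-05). A second Sox1 probe rose by 0.25 and the mean over both probes by 1.502. Sox2, a transcription factor gene of both pluripotent and neural cells, rose 1.73-fold (log2 change 0.79 ± 0.065). Zic2 rose 1.83-fold (log2 change 0.87 ± 0.064), Zeb2 rose 3.24-fold, and Ncam1, a neural cell adhesion gene, rose 2.75-fold. Among the members that fell was Pou3f1 (log2 change -0.43 ± 0.098, adjusted p = 0.0194), a transcription factor gene expressed in the epiblast and neural plate. The list was called higher (median 0.415, adjusted p = 0.00185; adjusted p = 0.204 with an estimated correlation). Of 13 anterior neural plate genes, 8 rose and 0 fell (median 0.982, adjusted p = 0.0024; adjusted p = 0.216 with an estimated correlation). Hesx1, a gene needed for forebrain formation, rose 4.95-fold (log2 change 2.31 ± 0.13), Lhx5 rose at least 2.0-fold, and Dmbx1, well above background on 1 EpiSC array, rose 4.08-fold. Lhx2 rose 1.98-fold (log2 change 0.98 ± 0.18), and Rax, an eye field gene, rose at least 1.71-fold (adjusted p = 0.0113). Without a filter on dim probes, the medians of the neural plate and anterior lists were 0.208 and 0.332. Six3 (log2 change 0.48 ± 0.44, adjusted p = 0.405) and Pax6 (log2 change -0.0059 ± 0.31, adjusted p = 0.989) were not well above background in either group. Otx2 (log2 change 0.18 ± 0.060, adjusted p = 0.0555) and Cdh2, which encodes N-cadherin (log2 change 0.12 ± 0.050, adjusted p = 0.109), did not pass.

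Of 15 neuronal differentiation genes, 9 rose and 2, Isl1 (-1.14) and Dcx (-1.03), fell. Tubb3, the neuronal beta-tubulin gene, rose 4.36-fold (log2 change 2.13 ± 0.082), Dll1, a Notch ligand gene listed here and in the Notch pathway, rose at least 3.51-fold, and Gap43 rose 2.39-fold. The neuronal list was called higher (median 0.644, or 0.523 with bounds, adjusted p = 0.00292; adjusted p = 0.204 with an estimated correlation). The posterior neural and axial list was not called (adjusted p = 0.542), and its median of -0.164 and mean of 0.272 differ in sign, the test's direction being up. Within it Irx3, a homeobox gene of the neural plate behind the forebrain, rose 18.1-fold (log2 change 4.17 ± 0.10, adjusted p = 7.56e-05), and Gbx2 rose 4.94-fold.

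Genes of pluripotency fell in part. Pou5f1, which encodes the core pluripotency factor Oct4, fell 1.72-fold (log2 change -0.79 ± 0.076, adjusted p = 0.00151), and Fgf5, a marker of the epiblast, fell 3.83-fold (log2 change -1.94 ± 0.091). Nanog, another pluripotency factor gene, rose 1.31-fold (log2 change 0.39 ± 0.054, adjusted p = 0.00438). Of 15 epiblast pluripotency genes 11 fell and 2, Nanog and Lin28a (0.48), rose (median -0.405, adjusted p = 0.014; adjusted p = 0.222 with an estimated correlation). Cdh1, which encodes E-cadherin, fell 1.15-fold (log2 change -0.20 ± 0.059, adjusted p = 0.0412). Of 14 naive pluripotency genes 9 fell and 1, Fbxo15 (0.79), rose. Dppa2 fell at least 7.7-fold, Tdh, which encodes threonine dehydrogenase, fell 5.82-fold (log2 change -2.54 ± 0.15), and Nr0b1 fell 4.08-fold. The naive list was called lower (median -1.20, adjusted p = 0.0283; adjusted p = 0.253 with an estimated correlation). This call ended under median scaling (adjusted p = 0.0724) and among genes above background on all 6 arrays (adjusted p = 0.15, the highest of a range from 0.00508).

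FGF and ERK targets fell almost throughout: 16 of 18 were lower and 1 was higher (median -0.933, adjusted p = 1.58e-05; adjusted p = 0.204 with an estimated correlation). Myc fell 5.45-fold (log2 change -2.45 ± 0.043, adjusted p = 6.52e-05), Etv4, a transcription factor gene induced by FGF, fell 4.37-fold, and Spry4, a feedback inhibitor of FGF signalling, fell 3.41-fold. Ier3, an immediate early gene, was the member that rose (0.80); like the other members named for moving against their list, it was chosen after its values were seen. Of 13 Wnt targets 8 fell and 2 rose (median -0.65, adjusted p = 0.0392; adjusted p = 0.481 with an estimated correlation). This call too ended under median scaling (adjusted p = 0.099, range 0.00927 to 0.099). T is also a member here. Fzd10, a Wnt receptor gene, fell 4.98-fold, Sp5, a Wnt-induced transcription factor gene, fell 4.67-fold, and Lgr5 fell 2.84-fold. The members that rose were Nkd1 (1.11) and Rnf43 (0.55), both feedback inhibitors of Wnt. BMP targets split, 2 rising and 3 falling of 9 (adjusted p = 0.537): Id3 rose 3.11-fold and Id1 1.9-fold, while Smad7, shared with the Nodal list, fell 12.4-fold and Id2 3.35-fold.

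Across all genes the 6 largest rises among genes well above background on every array of both groups were those of Actc1, the cardiac alpha-actin gene (43.2-fold, log2 change 5.43 ± 0.10), Tal2 (19.5-fold), Irx3, Irx5 (16.9-fold), Sez6 (14.6-fold) and the ephrin receptor gene Ephb1 (12.7-fold). Among the largest falls were those of Slpi, a secreted protease inhibitor gene (39.8-fold, log2 change -5.31 ± 0.066), Grm6 (29.6-fold), Shisa3 (29.0-fold), Tdgf1 and Lefty1. The highest bounds were those of Chrna4 (at least 7.14-fold), Cdk5r2 (at least 5.02-fold) and Ccdc184 (at least 4.95-fold) among rises, and of the neuropeptide Y gene Npy (at least 17.2-fold), Gm525 (at least 11.6-fold) and Ptgs1 (at least 8.35-fold) among falls.

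The remaining lists were not called on day 1. Sox9 rose 6.88-fold in the surface ectoderm and neural crest list, where 2 of 16 rose and 3 fell (adjusted p = 0.538). Fibroblast and feeder markers split 4 to 4 among 15 (adjusted p = 0.482), with Acta2 up 3.3-fold and Twist2 down 3.18-fold. Of 7 extraembryonic and trophoblast genes 6 fell, Plac1 at least 4.91-fold (adjusted p = 0.055, range 0.0243 to 0.209). Of 6 germ cell genes 4 fell and 1 rose (adjusted p = 0.203), Prdm1 falling 4.19-fold with 1 NPC1 array above background. In the Notch pathway list 5 of 11 rose and 4 fell (adjusted p = 0.193), with Lfng up 2.86-fold and Hes5 up 2.58-fold. Retinoic acid response genes split 3 to 3 among 8 (adjusted p = 0.663), Crabp2, a retinoic acid binding protein gene, rising 6.06-fold. Slc2a1, the glucose transporter gene, rose 3.3-fold and Egln3 2.63-fold in the glycolysis and hypoxia list, where 8 of 16 rose and 4 fell (adjusted p = 0.106). Cholesterol synthesis genes split 4 to 4 among 22 (adjusted p = 0.81; median -0.055 and mean -0.0254, test direction up). Unfolded protein and amino acid stress genes split 5 to 1 among 13 (adjusted p = 0.165) with Ddit4 up 2.48-fold, and p53 targets split 5 to 3 among 15 (adjusted p = 0.537; median -0.0699, mean 0.0983). In the cell cycle list 1 of 16 rose and 6 fell (adjusted p = 0.207; 3 rose and 1 fell in the value table), and of 10 housekeeping genes 1, Hprt, fell 1.25-fold (adjusted p = 0.409). Actb (log2 change 0.013 ± 0.052, adjusted p = 0.852) and Gapdh (log2 change -0.032 ± 0.057, adjusted p = 0.671) did not pass. The medians of the fibroblast, BMP, cholesterol, stress, p53, cell cycle and housekeeping lists changed sign under another scaling. Counts moved too. Cholesterol genes split 8 up to 2 down in the value table and 3 to 8 under median scaling. Stress genes split 6 to 1 and 3 to 3, and p53 targets 6 to 2 and 4 to 6.

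In all, 7394 of the 14772 genes (50.1%) passed an adjusted p of 0.05 by limma, 3169 higher and 4225 lower in NPC1. Of these, 1232 changed at least 2-fold in fitted values, 659 higher and 573 lower. The lower share was 57.1%, against 37.9% in the authors' value table and 71.2% under median scaling. Among genes changed at least 2-fold it was 46.5%, against 36.3% in the value table and 57% with normexp background correction, under which 502 genes passed. Without EpiSC replicate B 4840 genes passed. The call of Cdh1 ended in the authors' value table (adjusted p = 0.291), under quantile normalization (adjusted p = 0.493, range 0.00898 to 0.493), and so it did without EpiSC replicate A, NPC1 replicate A, EpiSC replicate B or NPC1 replicate B (adjusted p = 0.0995, 0.0993, 0.173 and 0.122). For Pou3f1 it ended without EpiSC replicate A, NPC1 replicate A or EpiSC replicate B (adjusted p = 0.0572, 0.0647 and 0.092, range 0.000138 to 0.092). For Rax it ended without NPC1 replicate B (adjusted p = 0.0545) and with normexp (adjusted p = 0.0645, range 0.00898 to 0.0645). Hprt lost it without EpiSC replicate B (adjusted p = 0.0576, range 0.000803 to 0.0576). Otx2 passed with normexp, quantile normalization and the value table (lowest adjusted p = 0.0119, highest 0.28). Cdh2 passed with quantile normalization, the value table and the mean of its probes (lowest adjusted p = 0.0136, highest 0.833). Counts of list members adjusted over the list alone were the same for 21 of the 24 lists. The others were the neural plate (3 fell), anterior neural plate (9 rose) and Wnt (3 rose) lists. With the normexp correction, which used another intensity measure and an offset of 50, 132 of the 345 called values of named genes were over 1.5 times smaller. So were 17 of the 36 medians of called lists.

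**Figure D1:**
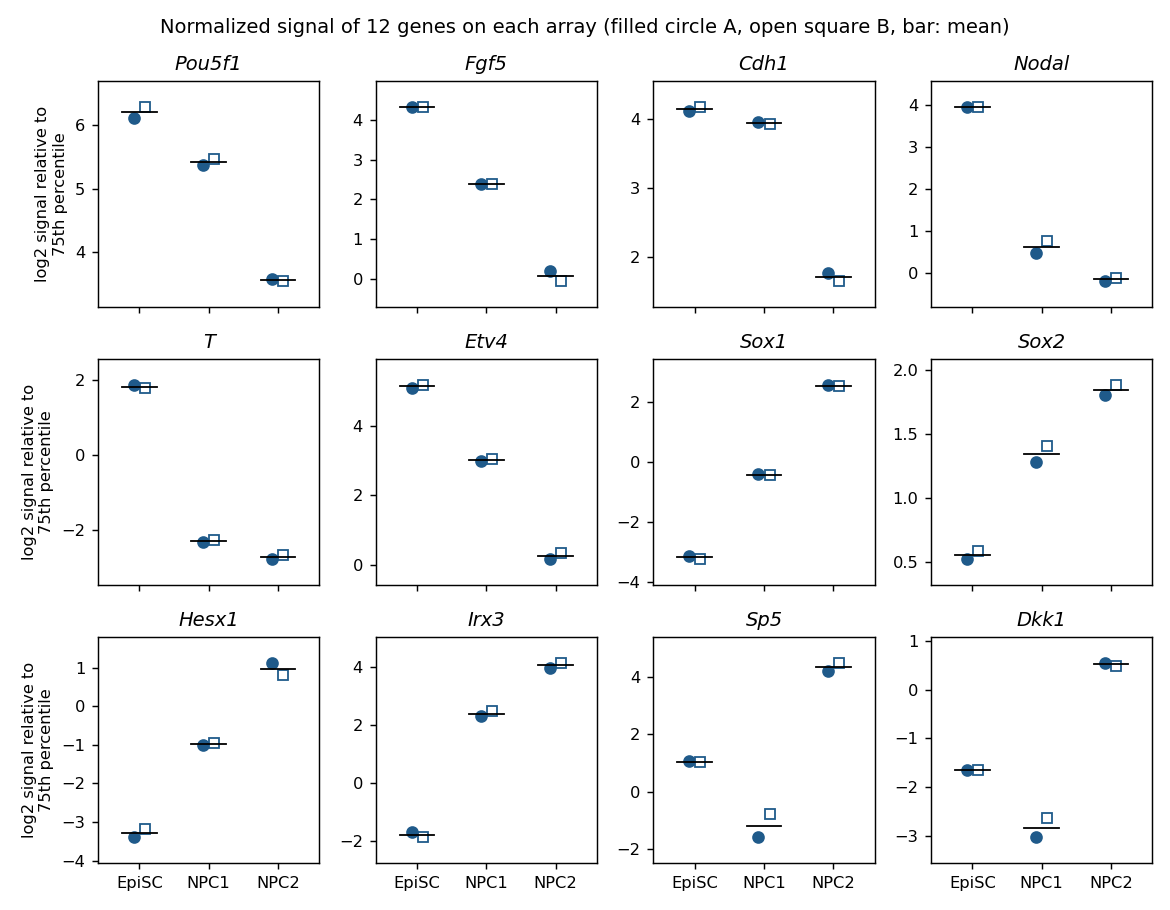
Normalized signal of 12 genes on each of the 6 arrays, as log2 relative to the array's 75th percentile (vertical axes, which differ by panel), by group (horizontal axis); the filled circle is culture A, the open square culture B and the bar their mean. Pou5f1 and Fgf5 are lower in NPC1 and lower still in NPC2, Cdh1 is 5.38-fold lower in NPC2, Nodal and T are low from NPC1, Sox1 rises 6.75-fold by NPC1 and 52.7-fold by NPC2, and Sp5 and Dkk1 are lowest in NPC1 and highest in NPC2.

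After 2 days, compared with EpiSC, genes of the neural plate were higher and most genes of pluripotency lower. Sox1 was 52.7-fold higher (log2 change 5.72 ± 0.057, adjusted p = 5.9e-06; second probe 1.82, mean of both 3.77). Hes3, a repressor gene of the Hes family, was at least 274-fold higher, and Hes5, a Notch target, was 11.5-fold higher. Pou5f1 was 6.32-fold lower (log2 change -2.66 ± 0.076), Fgf5 was lower (log2 change -4.26 ± 0.091), and Tdgf1 135-fold lower (log2 change -7.07 ± 0.11, adjusted p = 6.54e-06; 1 other probe -1.36). Cdh1 was 5.38-fold lower (log2 change -2.43 ± 0.059) and Cdh2 3.88-fold higher (log2 change 1.96 ± 0.050, adjusted p = 1.4e-05).

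The neural plate list was called higher, with 15 of 21 members rising and 4 falling (median 1.37, adjusted p = 0.000455; adjusted p = 0.204 with an estimated correlation). Sox2 rose 2.44-fold (log2 change 1.28 ± 0.065), Zic2 1.43-fold (log2 change 0.52 ± 0.064) and Pou3f2 at least 2.94-fold. The 4 that fell were Pou3f1 (4.38-fold, log2 change -2.13 ± 0.098), Nes, which encodes the intermediate filament nestin (-2.03), Zic5 (-1.62) and Gpm6a (-1.39). All 13 tested anterior neural plate genes, of 18 on the array, rose (median 3.24, or 2.48 with bounds). The list's adjusted p by camera was 1.98e-06, and 0.204 with an estimated correlation. The changes of 6 of the 13 are known only as bounds. These genes were above background on no EpiSC array, so they entered the test through the later groups alone. Dmbx1, a homeobox gene of the anterior brain, rose 227-fold (log2 change 7.82 ± 0.20; 1 EpiSC array above background) and Lhx5 at least 73.4-fold. Sp8 rose 40.4-fold (log2 change 5.33 ± 0.22; second probe 0.802, mean of both 3.07), Hesx1 19.0-fold (log2 change 4.25 ± 0.13) and Lhx2 9.45-fold. Fezf2 rose at least 5.57-fold, Six3 at least 3.25-fold, Pax6 at least 2.31-fold, Rax at least 1.92-fold and Otx2 1.71-fold (log2 change 0.77 ± 0.060).

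Of 14 posterior neural and axial genes 11 rose and 2, among them the hindbrain gene Egr2 (-2.41), fell (median 2.6, or 2.09 with bounds, adjusted p = 0.00131; adjusted p = 0.217 with an estimated correlation; median 1.73 without a filter on dim probes and 4.29 among genes above background on all 6 arrays). Of the list's 21 genes on the array, these 14 were tested. Irx3 rose 57.7-fold (log2 change 5.85 ± 0.10). The midbrain and hindbrain genes En1 and En2 rose (En1 at least 11.6-fold, En2 log2 change 4.32 ± 0.15), and Nkx1-2 rose 20.3-fold (log2 change 4.34 ± 0.13; a second probe 1.49). Notch pathway genes rose in 9 of 11 and fell in 0 (median 0.566, adjusted p = 0.000125; adjusted p = 0.204 with an estimated correlation). Among them were Dll1 (at least 26.6-fold), Hes5, Lfng, a modifier of Notch receptors (4.23-fold), and Notch2 (2.32-fold). Of 15 neuronal differentiation genes 8 rose and 3 fell (median 0.553, adjusted p = 0.0389; adjusted p = 0.222 with an estimated correlation). Neurog2, a proneural gene, rose at least 3.58-fold, Tubb3 rose 2.82-fold and Isl1 fell 4.6-fold. Dll1 belongs to this list too, and the other members that fell were Dcx (-1.03) and Neurod1 (-0.76). That call ended under quantile normalization (adjusted p = 0.0904), in the value table (0.0997) and on genes above background on all 6 arrays (0.153). It also ended without NPC2 replicate A (0.0505, median 0.282), over a range from 0.016.

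BMP targets rose in 5 of 9 and fell in 2 (median 1.08, adjusted p = 0.0401; adjusted p = 0.323 with an estimated correlation). Id3 was 18.2-fold higher (log2 change 4.19 ± 0.097, adjusted p = 1.19e-05), Id1 8.08-fold, and Msx1, a transcription factor gene of the neural plate border, 11.7-fold. Smad7 fell 13.7-fold and Gata3 fell (-1.38). The call ended under quantile normalization (adjusted p = 0.0904), in the value table (0.162) and without NPC2 replicate A (0.0573), over a range from 0.0196. The median moved to 0.691 without NPC2 replicate A, 0.47 without EpiSC replicate A and 1.72 without EpiSC replicate B. Wnt targets parted. Nkd1 rose 28.7-fold (log2 change 4.84 ± 0.13), Sp5 9.71-fold and Axin2, a general Wnt target, 6.74-fold, and T fell 23.3-fold (log2 change -4.54 ± 0.060). The list, with 5 of 13 up and 4 down, was not called (adjusted p = 0.353). Surface ectoderm and neural crest genes were not called either (8 up and 5 down of 16, adjusted p = 0.0653, range 0.0328 to 0.302). Pax3 rose 36.5-fold from 1 EpiSC array above background, Sox9 33.9-fold and Pax7 at least 13.9-fold. Retinoic acid response genes Crabp2 (22.5-fold), Stra6, a retinol transporter gene (at least 14.9-fold), and Crabp1 (5.41-fold) rose within a list that was not called (5 up and 3 down of 8, adjusted p = 0.126).

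All 11 Nodal signalling genes fell (median -3.81, adjusted p = 3.05e-05; adjusted p = 0.217 with an estimated correlation). Cer1 fell 54.3-fold (log2 change -5.76 ± 0.069), Lefty1 18.0-fold and Nodal 17.1-fold (log2 change -4.10 ± 0.10). FGF and ERK targets fell in 17 of 18 and rose in 0 (median -1.85, adjusted p = 1.19e-05; adjusted p = 0.204 with an estimated correlation). Etv4 fell 29.8-fold (log2 change -4.90 ± 0.078, adjusted p = 6.66e-06) and Etv5 fell as well (log2 change -3.46 ± 0.056). Spry4 fell at least 4.25-fold and Fosl1 at least 7.02-fold. Of 15 epiblast pluripotency genes 11 fell and 4 rose (median -2.43, adjusted p = 0.0167; adjusted p = 0.222 with an estimated correlation). The growth factor gene Fgf4 fell 30.0-fold, Utf1 21.2-fold and L1td1 21.1-fold. The members that rose were Nanog (1.76-fold, log2 change 0.82 ± 0.054), Lin28a (0.63), Sall4 (0.42) and Lin28b (0.36). Of 14 naive pluripotency genes 12 fell and 1 rose (median -2.28, or -2.04 with bounds, adjusted p = 0.00167; adjusted p = 0.205 with an estimated correlation). Tdh fell 41.0-fold, Dppa2 at least 7.76-fold and Nr0b1 at least 6.04-fold. Tbx3, a T-box gene also used in other tissues, rose at least 3.74-fold.

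Primitive streak and mesoderm genes fell in 10 of 16 and rose in 3, and the list was not called (median -1.92, adjusted p = 0.0895, range 0.0103 to 0.155). Eomes fell 17.0-fold and Mixl1 at least 4.57-fold. Of 11 endoderm genes 8 fell and 3 rose without a call (adjusted p = 0.28). Sox17 fell 7.36-fold (1 NPC2 array above background), Foxa2 fell 3.67-fold and the chemokine receptor gene Cxcr4 rose 17.0-fold. Fibroblast and feeder markers rose in 8 of 15 and fell in 3 (median 0.487, adjusted p = 0.126): Acta2 rose 6.02-fold, Prrx1 at least 4.99-fold and Postn at least 1.88-fold, and S100a4 fell 9.32-fold. Extraembryonic genes (1 up and 5 down of 7, adjusted p = 0.187) and germ cell genes (1 up and 4 down of 6, adjusted p = 0.355) were not called. Plac1 fell at least 4.95-fold, the growth factor gene Bmp4 rose 2.78-fold, and Kit, a receptor tyrosine kinase gene, rose 2.15-fold.

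Cholesterol synthesis genes fell in 18 of 22 and rose in 1, Tm7sf2 (0.49), by small amounts (median -0.504, adjusted p = 0.0024; adjusted p = 0.328 with an estimated correlation). Sc5d fell 1.85-fold (log2 change -0.88 ± 0.082), Pmvk 1.84-fold and Lss 1.63-fold, and the median was -0.277 under quantile normalization and -0.281 in the value table. Of 13 unfolded protein and amino acid stress genes 11 fell and 1, Ddit4 (0.75), rose (median -0.523, adjusted p = 0.0239; adjusted p = 0.217 with an estimated correlation). The cystine transporter gene Slc7a11 fell at least 4.33-fold, Trib3 2.9-fold and Atf3 2.86-fold. Quantile normalization ended this call (adjusted p = 0.054, range 0.00718 to 0.054; median -0.347), and the value table gave a median of -0.3. Lists of p53 targets (adjusted p = 0.532), cell cycle (0.482), glycolysis and hypoxia (0.803; median -0.0459, mean -0.0064, test direction up) and housekeeping genes (0.16) were not called. The medians of the last 3 changed sign under another scaling. Perp fell 2.98-fold, Ccne1, a G1 cyclin gene, 1.98-fold, Hprt 1.88-fold, and Slc2a1 rose 3.15-fold. Gapdh did not pass (log2 change -0.06 ± 0.057, adjusted p = 0.393). Actb, called lower (log2 change -0.20 ± 0.052, adjusted p = 0.0203), lay at 0.023 in the value table, where the call ended (adjusted p = 0.731, range 0.00631 to 0.731). The call also ended under quantile normalization (0.198) and without EpiSC replicate A (0.081), NPC2 replicate A (0.0975) or EpiSC replicate B (0.0886).

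The 6 largest rises of genes well above background on every array of both groups were those of Irx1, a homeobox gene (458-fold, log2 change 8.84 ± 0.15), Tal2 (254-fold, log2 change 7.99 ± 0.23), Pdzph1 (91.1-fold), the forkhead gene Foxb1 (85.6-fold), the nuclear receptor gene Nr2f1 (83.8-fold) and Irx5 (68.2-fold). The highest bounds were those of Hes3, Cbln1 (at least 82.6-fold) and Lhx5. The largest falls were those of Tdgf1, Psors1c2 (69.4-fold), Cer1, Trim67 (52.9-fold), Trh, the thyrotropin-releasing hormone gene (45.8-fold), and the phospholipase gene Pla2g10 (43.6-fold), with bounds for Slpi (at least 131-fold), Mab21l4 (at least 57.2-fold) and Aadac (at least 51.3-fold). In all, 10181 genes (68.9%) passed, 4180 higher and 6001 lower in NPC2, and 2943 changed at least 2-fold, 1432 higher and 1511 lower; 1648 did so with normexp. The lower share of calls was 58.9%, against 38.8% in the authors' value table, and 51.3% at 2-fold, against 38.5% there. Counts adjusted over the list alone were the same for 19 of the 24 lists. The others were the naive (13 fell), fibroblast (4 fell), germ cell (5 fell), Notch (11 rose) and cell cycle (11 fell) lists.

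**Figure D2:**
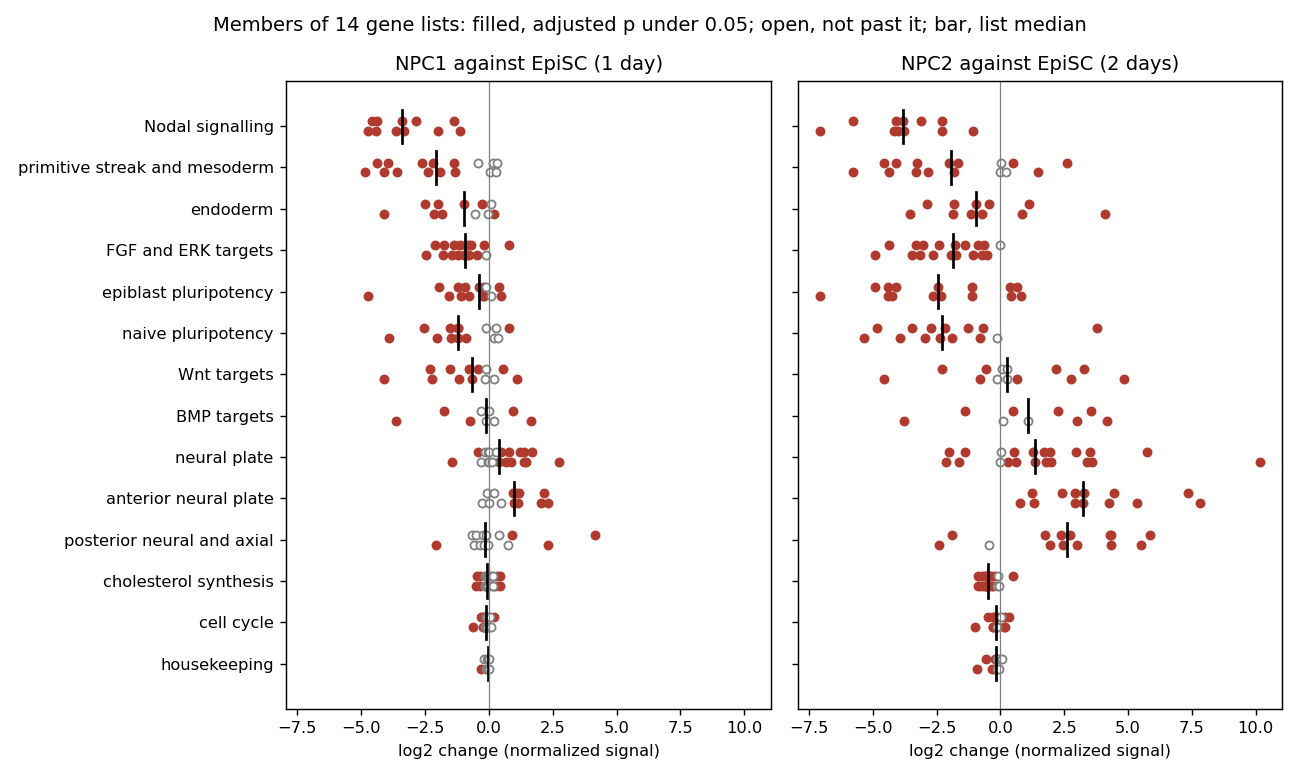
Log2 changes of the members of 14 gene lists, NPC1 against EpiSC on the left and NPC2 against EpiSC on the right; each point is a gene, filled where its adjusted p was under 0.05 and open otherwise, and the bar is the list's median. The Nodal signalling median lies at -3.42 and -3.81, the neural plate median at 0.415 and 1.37, and the anterior neural plate median at 0.982 and 3.24; the cell cycle and housekeeping medians, near 0, changed sign under another scaling.

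The comparison of NPC2 with NPC1 asked what differed between the first and the second day. Among the largest rises were those of Dmbx1, Nr2f1, Irx1 and Lhx5, which encode transcription factors. Dmbx1 rose 55.5-fold (log2 change 5.80 ± 0.20, adjusted p = 8.54e-05), Nr2f1 58.4-fold (log2 change 5.87 ± 0.15), Irx1 52.3-fold and Lhx5 36.6-fold. For rises, bounds were highest for Hes3 (at least 293-fold), the zinc finger gene Zfp503 (at least 73.4-fold) and Pax3, a gene of the dorsal neural tube (at least 38.7-fold). Sp5 rose 45.4-fold (log2 change 5.51 ± 0.27, adjusted p = 0.000186) after its fall on day 1. Scube2 rose 61.0-fold on the probe used (log2 change 5.93), while a second probe gave a log2 change of 3.06. The largest falls were those of Ltb, the lymphotoxin beta gene (28.0-fold, log2 change -4.81 ± 0.12), Stmn4 (16.4-fold), Ier3 (15.5-fold), the calcitonin receptor gene Calcr (14.4-fold), Fgf4 (13.9-fold) and Spp1, the osteopontin gene (log2 change -3.70 ± 0.16). Bounds were highest for falls of Il20ra (at least 8.54-fold), Cxcl1 (at least 7.71-fold) and Bcl11b (at least 7.59-fold).

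Anterior neural plate genes rose in 12 of 13 and fell in 0 (median 2.46, or 1.94 with bounds, adjusted p = 3.57e-07; adjusted p = 0.204 with an estimated correlation). Sp8 rose 21.1-fold (log2 change 4.40 ± 0.22; second probe 0.738, mean of both 2.57), Lhx2 4.78-fold, Hesx1 3.83-fold and Otx2 1.5-fold. Pax6 rose at least 2.47-fold and Six3 at least 3.47-fold (adjusted p = 0.00935; adjusted p = 0.0502 without NPC2 replicate A, range 0.000534 to 0.0502). Rax did not pass (log2 change 0.17 ± 0.20, adjusted p = 0.536). Neural plate genes rose in 14 of 21 and fell in 6 (median 1.03, adjusted p = 0.00167; adjusted p = 0.204 with an estimated correlation). Sox1 rose 7.81-fold (log2 change 2.97 ± 0.057; second probe 1.57), Cdh2 3.57-fold (log2 change 1.84 ± 0.050) and Sox2 1.41-fold. The falls were those of Nes, Pou3f1 (3.25-fold), Zic5, Gpm6a, Zic1 and Zic2 (1.28-fold, adjusted p = 0.00965; adjusted p = 0.0544 without NPC2 replicate B, range 0.00703 to 0.0544). Posterior neural and axial genes rose in 11 of 14 and fell in 1, Egr2 (-1.85; median 2.28, or 1.83 with bounds, adjusted p = 6.98e-05; adjusted p = 0.204 with an estimated correlation). En1 rose at least 12.4-fold, En2 25.4-fold, Nkx1-2 10.7-fold (log2 change 2.06 as the mean of its probes) and Hoxb3 at least 2.73-fold. Neuronal differentiation genes split, 4 up and 7 down of 15 (adjusted p = 0.899). The list's median of 0.00417 and mean of 0.185 stand against a test direction of down. Neurog2 rose at least 3.82-fold, and Neurod1 and Elavl3 fell 2.64-fold and 2.2-fold.

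The lists of BMP, Notch, retinoic acid and Wnt genes were called higher in NPC2 than in NPC1. BMP targets rose in 6 of 9 and fell in 1, Gata3 (-1.08; median 1.84, adjusted p = 0.00171; adjusted p = 0.216 with an estimated correlation). Msx1 rose 19.3-fold (log2 change 4.27 ± 0.081) and Id3 5.86-fold. Notch pathway genes rose in 9 of 11 and fell in 1, Dll3 (-0.20; median 0.638, adjusted p = 8.58e-05; adjusted p = 0.204 with an estimated correlation). Dll1 rose 7.57-fold, Hes5 4.47-fold and the ligand gene Jag1 2.72-fold. Retinoic acid response genes rose in 6 of 8 and fell in 0 (median 1.12, adjusted p = 0.00167; adjusted p = 0.204 with an estimated correlation; median 0.688 without a filter on dim probes). Stra6 rose 6.61-fold, Crabp1 4.08-fold and Cyp26a1, which encodes a retinoic acid degrading enzyme, 2.51-fold. Wnt targets rose in 7 of 13 and fell in 3 (median 0.187, adjusted p = 0.0402; adjusted p = 0.481 with an estimated correlation). Nkd1 rose 13.3-fold (log2 change 3.74, and 2.34 on a second probe), Axin2 10.6-fold, and Dkk1, a Wnt inhibitor gene, 10.3-fold. Lgr5 (-0.80), T (-0.43) and Lef1 (-0.34) fell. The Wnt call ended under quantile normalization (adjusted p = 0.0869), in the value table (0.0822; median 0.29) and without NPC1 replicate B (0.0598) or NPC2 replicate B (0.0759), over a range from 0.00694. Surface ectoderm and neural crest genes rose in 8 of 16 and fell in 5 (median 0.864, adjusted p = 0.0385; adjusted p = 0.372 with an estimated correlation). Pax7 rose at least 14.8-fold and Msx2 5.23-fold, Msx1 and Msx2 being BMP targets as well. Grhl2, an epithelial transcription factor gene, fell (-1.50). This call ended under quantile normalization (adjusted p = 0.0999), in the value table (0.156) and on genes above background on all 6 arrays (0.209, median 0.274). It ended too without NPC2 replicate A (0.0505), over a range from 0.00856.

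Both pluripotency lists were called lower again. Pou5f1 fell 3.67-fold (log2 change -1.87 ± 0.076, adjusted p = 0.000114), Fgf5 4.99-fold, Cdh1 4.67-fold (log2 change -2.22 ± 0.059), Utf1 10.9-fold and L1td1 9.12-fold. Nanog rose 1.34-fold (log2 change 0.43 ± 0.054). The epiblast list held 11 falls and 3 rises (Nanog, Sall4 and Lin28b) among 15 (median -1.90, adjusted p = 0.00225; adjusted p = 0.207 with an estimated correlation). The naive list held 10 falls and 1 rise (Tbx3, at least 3.99-fold) among 14 (median -1.26, or -1.21 with bounds, adjusted p = 0.00131; adjusted p = 0.204 with an estimated correlation). FGF and ERK targets fell in 12 of 18 and rose in 3, Spry1 (0.58), Myc (0.52) and Spred1 (0.47; median -0.72, or -0.661 with bounds, adjusted p = 0.00302; adjusted p = 0.216 with an estimated correlation). Etv4 fell 6.81-fold and Etv5 5.56-fold. Of 11 Nodal signalling genes 7 fell and 3, among them Lefty1 (0.40) and Cfc1 (0.92), rose, and the list was not called (adjusted p = 0.191). Cfc1 lost its call without NPC2 replicate A or NPC2 replicate B (adjusted p = 0.0722 and 0.0533, range 0.00176 to 0.0722). Nodal fell 1.71-fold and T 1.35-fold. Sox17, on 1 NPC2 array above background, fell 1.83-fold (adjusted p = 0.0401). That call ended with normexp (adjusted p = 0.069) and in the value table (0.0539). It ended without EpiSC replicate A or B, where the log2 change stayed at -0.87 and only the estimate of spread changed. The Sox17 call also ended without NPC1 replicate A (log2 change -0.95), NPC1 replicate B (-0.79) or NPC2 replicate B (-0.52), over a range of adjusted p from 0.0029.

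All 13 unfolded protein and amino acid stress genes fell from day 1 to day 2 (median -0.553, adjusted p = 3.58e-05; adjusted p = 0.204 with an estimated correlation). Atf3, a stress-induced transcription factor gene, fell 3.33-fold, Trib3 3.03-fold and Chac1 2.15-fold. Cholesterol synthesis genes fell in 17 of 22 and rose in 0 (median -0.495, adjusted p = 0.00011; adjusted p = 0.237 with an estimated correlation). Hmgcs1, which encodes an early enzyme of the pathway, fell 1.49-fold and Msmo1 1.54-fold. Of 15 p53 targets 8 fell and 2, Sesn1 (0.21) and Zmat3 (0.30), rose (median -0.314, adjusted p = 0.033; adjusted p = 0.448 with an estimated correlation). Perp fell 1.94-fold and Mdm2, which encodes a negative regulator of p53, 1.65-fold. Endoderm (5 up and 3 down of 11, adjusted p = 0.177) and primitive streak and mesoderm genes (6 up and 4 down of 16, adjusted p = 0.592) were not called; for the latter the median was -0.0749, or 0.144 with bounds, and the mean 0.221, the test's direction being up. Nor were fibroblast (8 up and 4 down of 15, adjusted p = 0.202), extraembryonic (2 up and 3 down of 7, adjusted p = 0.513) and germ cell genes (1 up and 1 down of 6, adjusted p = 0.663; median 0.142, mean -0.291, test direction up). Glycolysis (0 up and 6 down of 16, adjusted p = 0.207), cell cycle (1 up and 2 down of 16, adjusted p = 0.829; median -0.0121, mean -0.0243, test direction up) and housekeeping genes (0 up and 5 down of 10, adjusted p = 0.182) were not called either. The medians of the streak, glycolysis and cell cycle lists changed sign under another scaling, and that of the neuronal list with normexp (-0.0145). Cell cycle genes split 5 up and 1 down under quantile normalization and 6 up and 1 down in the value table, and housekeeping genes 1 up and 2 down, and 1 up and 1 down. Foxa2 rose 4.63-fold and Evx1 at least 9.3-fold, Evx1 being above background on no NPC1 array, and Cxcr4 rose 24.9-fold from 1 NPC1 array above background. Gapdh did not pass (log2 change -0.028 ± 0.057, adjusted p = 0.72). Actb, called lower (log2 change -0.21 ± 0.052, adjusted p = 0.0245), lost its call under quantile normalization (adjusted p = 0.112) and in the value table (0.176). Actb lost it too without EpiSC replicate A or B, where its log2 change stayed at -0.21 and only the estimate of spread changed. The call also ended without NPC1 replicate A (log2 change -0.18), NPC2 replicate A (-0.18) or NPC2 replicate B (-0.25), over a range of adjusted p from 0.0216.

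Between the 2 days 6996 genes (47.4%) passed, 3045 higher and 3951 lower in NPC2, and 1608 changed at least 2-fold, 694 higher and 914 lower; 701 did so with normexp. The lower share of calls was 56.5%, against 41% in the authors' value table, and 56.8% at 2-fold, against 49.2% there. Counts adjusted over the list alone were the same for 20 of the 24 lists. The others were the epiblast (4 rose), surface ectoderm (9 rose), FGF and ERK (14 fell) and p53 (9 fell) lists. Relative to the scaling used here, the authors' value table moved the median log2 change of all genes by 0.12 for NPC1 against EpiSC, 0.223 for NPC2 against EpiSC and 0.103 for NPC2 against NPC1. Median scaling moved it by -0.105, -0.0979 and 0.00732. With an estimated correlation, camera called 0 of the 72 tests of the 24 lists in the 3 comparisons (17 at an unadjusted p under 0.05), against 36 with the preset correlation of 0.01. The fry test, which takes a list by itself, called 60. It gave the other direction than camera in 5 tests, none of them called by either: the surface ectoderm list on day 1, the Wnt list after 2 days, and the streak, germ cell and cell cycle lists in NPC2 against NPC1.

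**Figure D3:**
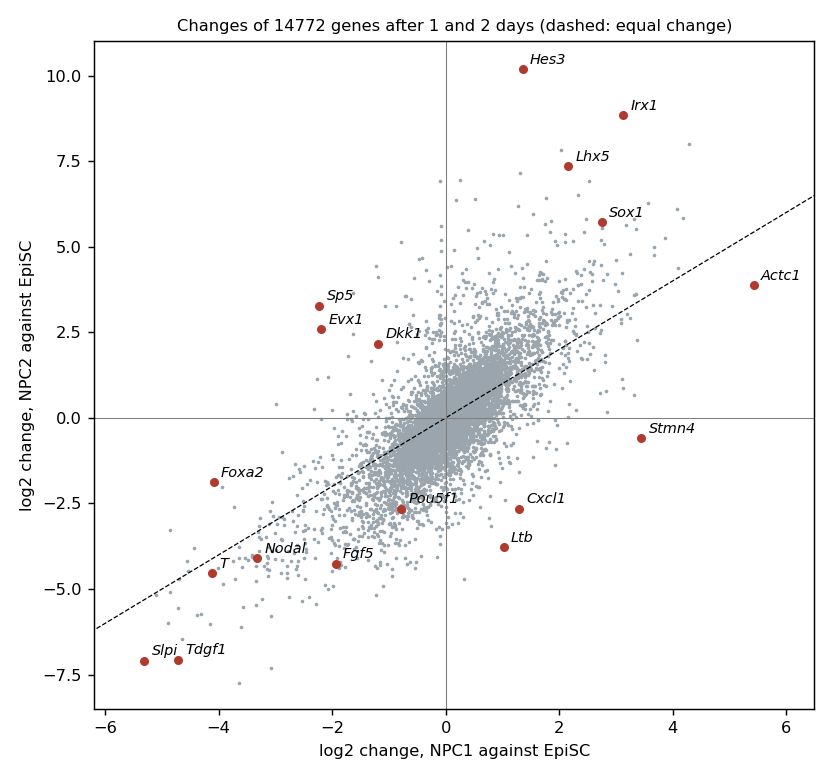
Log2 change of each of the 14772 genes after 1 day (NPC1 against EpiSC, horizontal axis) and after 2 days (NPC2 against EpiSC, vertical axis), as fitted values that include genes not above background in a group; the dashed line marks equal change and 18 genes are named. Tdgf1, at -4.72 and -7.07, lies in the lower left, Irx1 and Hes3 rise far above the dashed line, and Sp5 and Dkk1 lie in the upper left, lower after 1 day and higher after 2.

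Changes of the first day were compared with those after 2 days. Among genes called in both comparisons with EpiSC, 2542 were higher in both, such as Sox1, Irx3, Hesx1 and Crabp2. Lower in both were 3666, such as Tdgf1, Cer1, T, Nodal, Fgf5 and Etv4, and 374 moved in opposite directions, such as Sp5 and Dkk1. Independent lists of the same lengths would share 896.7, 1716 and 2483 genes. Simulated unchanged groups set against the same EpiSC arrays shared 0, 0.02 and 0 on average over 100 simulations. With no gene changed, almost none passes in either comparison, so these simulated counts give no baseline for the shared EpiSC arrays. The log2 changes correlated at r = 0.7559 across genes (0.499 in the simulations), with a covariance of 0.5425 (0.00965 in the simulations). With NPC1 set against EpiSC replicate A alone and NPC2 against EpiSC replicate B alone, a split chosen after the data were examined, 1851, 2196 and 200 genes were shared, where independent lists would share 573.1, 867.5 and 1424. The other way round gave 1844, 2392 and 210 (565.1, 933.1 and 1455), and the covariances were 0.5287 and 0.5289. Each lone EpiSC array was assumed to vary like the other groups. Called on day 1 and again from day 1 to day 2, 1385 genes rose and rose again, including Sox1, Irx1 and Hes5, and 1844 fell and fell again, including Pou5f1, Fgf5 and Etv4. Another 634 rose and then fell, including Actc1, Ier3 and Tubb3, and 488 fell and then rose, including Sp5, Dkk1, Axin2 and Foxa2. In 100 simulations with no change from day 1 to day 2, at most 1 gene took any of these paths. The adjustment lets almost no gene pass between the days there, so this count gives no rate of chance paths. Changing at least 2-fold each time in fitted values, 49 genes fell and then rose and 58 rose and then fell; with dim groups at their bounds these were 42 and 53.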

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

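The simulation, the leaving out of each NPC1 array and the counts at bounds were chosen only after the pattern they bear on had been seen. Genes of the Wnt response were among those that moved one way on day 1 and the other way by day 2. In all, 17 genes changed at least 2-fold in opposite directions after 1 day and after 2 days, each against EpiSC, with a group not above background at its bound. For 4 of these, named by the naming rule, the difference between the 2 days is the tested comparison of NPC2 with NPC1. Sp5, a Wnt-induced transcription factor gene, lay at -2.22 after 1 day and 3.28 after 2 (difference 5.51 ± 0.27, adjusted p = 0.000186), and Dkk1, a secreted Wnt inhibitor gene, at -1.19 and 2.17 (difference 3.36 ± 0.13, adjusted p = 0.000105). The lymphotoxin gene Ltb lay at 1.02 and -3.78 (difference -4.81 ± 0.12, adjusted p = 5.86e-05). The chemokine gene Cxcl1 lay at 1.29 after 1 day and was not above background in NPC2, where only bounds are known: -1.66 or lower against EpiSC and -2.95 or lower against NPC1 (adjusted p = 2.63e-05).

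More widely, 49 genes (42 with dim groups at their bounds) fell at least 2-fold on day 1 and rose at least 2-fold from day 1 to day 2, both calls resting on the same NPC1 arrays. The 100 simulations without a change from day 1 to day 2 gave at most 1 such gene, 0.0204 of the observed number. With no gene changed between the days, the adjustment lets almost none pass, whatever chance values the arrays share. The simulations therefore do not decide whether such values explain the 49 genes. With either NPC1 array left out, most of the 49 genes kept both calls (lowest share 0.939). A gene with 1 deviating NPC1 array has a wide spread between duplicates and would seldom have passed both tests that picked these genes. The selection thus largely fixed this share, and it does not decide whether 1 deviating array had a part. The Wnt list did not move as one: of its 13 members 4 (Sp5, Dkk1, Fzd10 and Axin2) fell and then rose, T and Lgr5 fell both times, and Nkd1 and Rnf43 rose on day 1. Whether the change of medium, the age of the culture or the neural plate condition set it was not tested.

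Of 14072 detected probes without a gene name, 1896 changed at least 2-fold in NPC2 against EpiSC, 1058 higher and 838 lower, and 1035 of them were among the 7495 probes designed to genomic intervals.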

How the results depend on the processing

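Chosen after the data were examined were the 2-fold counts by scaling, the 5 lists of the last part, the counts without each NPC1 array, the split of the EpiSC arrays, the counts at bounds and the markers below the 75th percentile. Of the values under alternatives, 111 counts of genes were within 1.5 times the main count and 18 were not. Of the list tests 980 kept their side of the threshold, 41 gained a call and 59 lost one. These 980 include uncalled lists whose direction changed, such as the 5 tests in which fry gave the other direction than camera. They also include uncalled lists whose median changed sign under another scaling. Of the values of named genes 4139 kept their side, 6 gained a call, 100 lost one and 3 reversed. The reversed values were those of Sdha and Actb in NPC2 against EpiSC. Sdha (log2 change -0.22) lay at 0.046 under quantile normalization and 0.0072 in the authors' value table, and Actb (-0.20) at 0.023 in the value table. Relative to the main scaling, the value table moved all genes of this comparison by 0.223, which accounts for the reversals there. The cause of the reversal under quantile normalization was not tested. Counts for NPC1 against EpiSC, NPC2 against EpiSC and NPC2 against NPC1 moved by construction to 1232, 2943 and 1608 at 2-fold or more (shared changes 1024 of 6208), to 11133, 18275 and 10687 with every probe by itself (2251, 5678 and 2869 at 2-fold), and at an adjusted p under 0.01 to 4404 (first), 4362 (last) and 3771 (shared). Normexp gave 502, 1648 and 701 at 2-fold. It changed the intensity measure, the background correction and the offset together, and the offset was not varied by itself. Without 1 array the counts ranged over 4840 to 6673 (lowest without EpiSC replicate B), 8554 to 10249 and 5002 to 6152, at 2-fold over 1208 to 1235, 2897 to 2957 and 1559 to 1619, and shared changes over 4147 to 5447. Split between the comparisons, with 1 EpiSC array each and fewer residual degrees of freedom, shared changes were 4047 and 4236. With the culture letter as a replicate block the counts were 6815, 9867 and 6482 (2-fold 1222, 2940 and 1601; shared 5782), and 1 list gained a call. It ended 3 list calls, neuronal (adjusted p = 0.0536) and BMP (0.0536) in NPC2 against EpiSC and surface ectoderm (0.0541) in NPC2 against NPC1, and 5 calls of named genes, Cdh1 (0.0679), Slc7a11 (0.0539) and Pcna (0.0624) in NPC1 against EpiSC and Sox17 (0.0713) and Actb (0.0506) in NPC2 against NPC1. No label says that the letters pair cultures across the groups. Across genes, A minus B differences correlated at 0.00799 (EpiSC and NPC1), 0.00626 (EpiSC and NPC2) and -0.0448 (NPC1 and NPC2). These values give no sign of a pairing but cannot exclude it. Of called values of named genes, 132 were over 1.5 times smaller with normexp, 16 moved as far under quantile normalization, 18 in the value table, 5 with the mean of all probes, 1 with median scaling and 1 without NPC2 replicate B (Sox17, NPC2 against NPC1). Called list medians kept their sign under each of these settings. Camera with an estimated correlation called 0 of 72 tests (lowest adjusted p = 0.204, 17 at an unadjusted p under 0.05), partly because limma then uses 3 degrees of freedom, and fry called 60. Slide and scan blocks were not run, all arrays sharing 1 of each. Signal over background limits dim genes: a change of a gene not well above background in a group is known only as a bound.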

Other observations

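The gene lists of this part and its tests of scaling, immune cells and fibroblasts were chosen only after the results had been seen, and some members were picked from called genes, so their counts and medians describe chosen genes, and the camera tests run on these lists are left out. Interferon-induced and antigen presentation genes were lower: 15 of 20 fell after 1 day and 16 after 2 days. The medians were -1.73 and -2.83, or -0.88 and -2.42 with bounds. After 2 days Psmb8, an immunoproteasome subunit gene, was 27.0-fold lower (-4.75 ± 0.060 on the log2 scale). The guanylate-binding protein gene Gbp2 was 23.9-fold lower, Gbp4 at least 33.3-fold and the transcription factor gene Irf1 14.2-fold. On day 1 H2-D1 (0.27), B2m (0.29) and Cxcl10 (0.76) rose, and after 2 days B2m, H2-D1 and Tap1 were among the 4 that did not pass. From day 1 to day 2, 15 fell and 1, Tap1 (0.22), rose. Of 20 genes of epithelial keratins and junctions 3 rose and 9 fell on day 1. After 2 days 19 of 20 had fallen and 1, Cldn3 (0.38), had risen (median -2.48, or -2.3 with bounds). All 20 fell from day 1 to day 2 (median -2.14). After 2 days Sfn was 31.7-fold lower, the tight junction genes Cldn6 and Cldn7 13.3-fold and 7.17-fold, and the simple epithelial keratin genes Krt19, Krt8 and Krt18 9.47-fold, 3.8-fold and 3.26-fold. Krt7 is also in the extraembryonic list.

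Actin cytoskeleton genes and targets of serum response factor rose on day 1 in 12 of 19 and fell in 2 (median 0.918, or 0.632 with bounds). After 2 days their median was -0.17 and their mean 0.131. From day 1 to day 2 they fell in 16 and rose in 2 (median -0.998). Actc1, the cardiac alpha-actin gene, rose 43.2-fold on day 1, the myosin light chain genes Myl3 and Myl4 10.4-fold and 8.18-fold, and the skeletal actin gene Acta1 6.02-fold, while Ccn2 and Ccn1 fell (-1.54 and -0.90). Acta2 and Tagln are fibroblast markers too. The members that rose from day 1 to day 2 were Myl4 (0.68) and Acta2 (0.86). Dorsal midbrain and roof plate genes rose in 9 of 18 on day 1, where Msx1 fell (-0.72). Their median was 0.539, or 0.849 without the 4 genes well above background on no EpiSC or NPC1 array. After 2 days 17 had risen (median 5.18, or 4.59 with bounds), and 17 rose from day 1 to day 2 (median 4.41, or 4.08 with bounds). After 2 days Wnt1, a signalling gene of the midbrain and roof plate, was 7.99-fold higher, Irx2 40.7-fold, Dbx1 at least 29.2-fold, Lmx1a, a roof plate transcription factor gene, at least 35.3-fold and En1 at least 11.6-fold. Dmbx1, En1, En2, Wnt1, Msx1, Msx2, Pax3 and Pax7 also stand in lists described above.

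More genes were called lower than higher in each comparison (57.1%, 58.9% and 56.5% lower). The scaling of the arrays could account for this split. The authors' value table differs from the scanner signal by 1 constant per array and so moves all genes of a comparison alike. With it the lower share was 37.9% in NPC1 against EpiSC, 38.8% in NPC2 against EpiSC and 41% in NPC2 against NPC1. In the same order, quantile normalization gave 48.7%, 49.4% and 47.7%, and median scaling 71.2%, 66.6% and 55.1%. Which scaling fits the RNA content of the cells was not tested, so the direction of small changes shared by many genes stays open.

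A loss of immune cells, or of fibroblasts or feeder cells, as the whole cause of the fall of interferon-associated genes needs the markers of those cells to fall by about as much after 2 days, a median of -2.42 with bounds. Immune cell markers had a median log2 change of -0.00824 (95% bootstrap interval -0.698 to 0.303; above the interferon median by 0.494 to 4.44), and of 14 with a probe 10 were tested and 3, among them Lyz2 and Tyrobp, were above background on no array. Fibroblast and feeder markers had a median of 0.487 (-0.557 to 0.91 with bounds; above the interferon median by 0.869 to 5.16), with Col1a1 at 1.05 and 1.23 and Tagln at 5.58 and 5.42, in log2 relative to the 75th percentile, in EpiSC and NPC2. Among markers below the 75th percentile, where the EpiSCs' own signal hides less, the medians were -0.194 (-0.784 to 0.303) and 0.222 (-1.49 to 1.14). Both lay above the interferon median by more than the spread (by at least 0.279 and 0.0623), although Aif1 (-2.25), S100a4 (-3.22) and Twist2 (-1.49) fell. The intervals resample genes and do not measure the spread between cultures. The interferon list was chosen after the results were seen, so its median is a selected reference. For immune cells these values argue against a loss as the whole cause. For fibroblasts and feeder cells the question stays open. Below the 75th percentile the interval of their markers reached -1.49, past the limit set for this test, and the margin was only 0.0623. A loss as part of the cause, a change within the cells, and an effect of the culture condition or of time in culture stay open and were not tested.

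The test of immune cell markers replaced an earlier comparison of levels between probes, after the value of that comparison, which spoke against immune cells, had been seen.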
